A study of Arabidopsis thaliana with 6 samples.

How the data were processed

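The study measured messenger RNA in whole seedlings of *Arabidopsis thaliana*, accession Col, and in seedlings labelled bbx4-1, a name for a mutant of the B-box gene BBX4. Per the labels, the seedlings grew for 4 days at 22 °C in constant red light, and 3 biological replicates of each genotype make up the 6 samples of the series. Per the labels' protocols, total RNA was extracted with a plant RNA kit, and libraries were made after poly(A) enrichment by fragmentation, cDNA synthesis, adaptor ligation, size selection and PCR. The libraries had no molecular identifiers that the labels mention, so PCR copies could not be told apart from separate fragments. The intervals given here cover counting error only, and may be too narrow even for that.

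The deposited data are 2 tables, 1 per genotype, with the columns headed WT and BBX4, each a single column of FPKM values (fragments normalised to transcript length in kilobases and to the number of mapped fragments) given to 2 decimals. Per the submitters' processing notes, the authors used HISAT2 2.1.0, edgeR 3.0.8 and the genome build TAIR10; their roles and order are not given in the sources used here, nor are the counting tool, the annotation release, the use of strand or any filter. The sample descriptions tie the column headed BBX4 to the bbx4-1 samples. The design text says that the 3 replicates of a genotype were combined, and the tables hold no column per replicate. The deposited FPKM are therefore printed as the authors' combined values, without SD or n. FPKM are not counts and each genotype has 1 column, so no test was run and no p-value is given. The design fixed before the data were examined named this case. A difference between the columns has no replicate check. Reads of overlapping or antisense genes, and of near-identical gene copies, may have been divided in ways that the sources used here do not describe.

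Depth was estimated from the low values. A transfer RNA gene with a single fragment has an FPKM equal to a constant divided by its length, and the constant falls as depth rises. Among transfer RNA genes of at most 75 bp, the product of FPKM and length for the lowest values above 0 fell into 2 narrow groups in the wild-type column (9 and 11 genes) and 3 in the bbx4-1 column (5, 7 and 6 genes). If the deposited value is the mean of 3 libraries' FPKM, these groups correspond to libraries of 17.8 and 16.0 M fragments for wild-type, with libraries of nearly equal depth falling into 1 group, and of 18.5, 16.7 and 15.5 M for bbx4-1. The sum over the 3 libraries was then between 49.7 and 51.6 M fragments for wild-type, depending on which group holds 2 libraries, and 50.7 M for bbx4-1, so which column was deeper is not established. The median product over these genes, which corresponds to 48.1 and 49.8 M fragments, served as the constant for approximate fragment numbers, and makes them slightly smaller than the sums would. Multiplying FPKM by the length of all annotated exons in the TAIR10.1 reference annotation and dividing by that constant gave an approximate number of fragments per gene. The counting standard error (SE) of a log2 ratio was taken from those numbers. The 95% counting interval of a log2 ratio is that ratio plus or minus 1.96 SE. For an FPKM ratio, the exact (Clopper-Pearson) 95% counting interval was taken from the same numbers, and the 2 kinds of interval can differ for single genes. Both are approximate, because the authors' gene lengths are not given in the sources used here and because they leave out the variation between seedlings.

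Values were compared as log2(FPKM + 1) in the bbx4-1 column minus log2(FPKM + 1) in the wild-type column. The pseudocount of 1 makes this log2 ratio understate the change of genes with low values, so FPKM are given beside it at least for the named genes with mean FPKM under 5. Loci with a mean FPKM of at least 1 over both columns were kept, and a 2-fold difference on this scale was the threshold for counting genes. Values were used as deposited, with no further scaling. Of the 33602 loci in each table, 32835 matched a gene of the TAIR10.1 RefSeq annotation by locus identifier. That annotation supplied symbols, lengths and the coordinates printed for BBX4 and its neighbours.

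Before the data were examined, 28 gene lists with 507 entries were fixed, covering light signalling, photosynthesis, pigments, growth, hormones, stress, nutrition, the circadian clock, other organs and reference genes. An entry was kept where its symbol matched the annotation's symbol or synonyms for that locus, which held for 488 entries and dropped 19. For each list, the median log2 ratio of members with mean FPKM of at least 1 was placed among the medians of 10000 random lists of the same size, matched on mean FPKM in 10 bins. A list is called above or below where its median lay over the 97.5th or under the 2.5th percentile. Such a percentile describes these 2 columns and is not a p-value. The genes named in the text were set by a rule, also fixed in advance: BBX4, the 12 nuclear genes with the largest rise and the 12 with the largest fall among those with mean FPKM of at least 5, and up to 3 highest and 3 lowest members of each list. The neighbours of BBX4 were taken by position. Other genes outside the rule are said to have been chosen after their values were seen.

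The counting and list procedures were tested on simulated tables of 18740 genes, built as the mean of 3 libraries at the depths above with the same 2 columns. Of 50 genes changed 3-fold upwards, 96% passed the 2-fold threshold, and all 50 of those changed 4-fold upwards did. Of genes lowered 3-fold and 4-fold, 68% and 86% passed. Of 18540 unchanged genes, 3 passed. Of 200 unchanged lists of 15 genes, 5.5% fell outside the central 95%, and 95% of 40 lists raised by 0.2 on the log2 scale lay above the 97.5th percentile. These simulated lists were drawn at random from all genes, whereas members of the real lists are related and some are shared between lists. The 5.5% is therefore near what the procedure builds in, and need not hold for the real lists. In a separate simulation of 464 transfer RNA genes at the bbx4-1 depths alone, the largest error of a library depth was 0.694%. The simulated libraries of the 18740 genes held counting error and a fixed amount of random variation between libraries, drawn separately for each gene. That amount was not estimated from these data, so the rates need not hold for the real variation between seedlings. The depth simulation held counting error only.

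The alternatives tried were pseudocounts of 0.1 and 5, and rescaling by trimmed means of log ratios (TMM) computed on the FPKM. Also tried were rescaling to equal totals, no filter, a filter at mean FPKM 5, and fold thresholds of 1.5 and 3. Random lists without matching were tried, as were lists without the 10% of members with the lowest mean FPKM. Keeping all listed loci, using nuclear loci only, and dropping BBX28 to BBX32 from the B-box list were added after the data were seen. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures used matplotlib 3.10.9.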

Results

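Transcript levels were compared between wild-type Col seedlings and seedlings labelled bbx4-1 after 4 days in constant red light, to find genes whose expression depends on BBX4, a B-box zinc finger protein also known as CONSTANS-LIKE 3 (COL3). Each genotype had 3 biological replicates, which the authors combined into 1 FPKM value per locus. Each table listed 33602 loci, of which 33323 were nuclear, 133 plastid and 146 mitochondrial. If the deposited value is the mean of 3 libraries' FPKM, single transfer RNA fragments put the summed depth at about 49.7 to 51.6 M fragments for wild-type and 50.7 M for bbx4-1. Which column was deeper is therefore not established. FPKM summed to 790456 in the wild-type column and 792874 in the bbx4-1 column. A value of 0 was listed for 7643 loci in wild-type, 7868 in bbx4-1 and 6411 in both. No column per replicate was available, so the differences below have no replicate check and no test, and the intervals cover counting error only.

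BBX4 itself went against the label. The column headed BBX4 is tied to the bbx4-1 samples by their descriptions, and is called the column labelled bbx4-1 here. The BBX4 transcript stood at 88.97 FPKM in wild-type and 1095.7 FPKM in that column, which is 12.3-fold higher (95% counting interval 11.98 to 12.66), or 3.61 on the log2(FPKM + 1) scale (counting SE 0.020). It ranked 1181st among nuclear loci in wild-type and 70th in the column labelled bbx4-1. BBX4 (AT2G24790) lies on chromosome 2, positions 10566836 to 10568145 of TAIR10.1, on the forward strand. Its main model has 2 exons, 10566836 to 10567537 and 10567641 to 10568145, with the coding sequence starting at 10566959 in the first exon and ending at 10567946 in the second. The tables give 1 value for the whole gene, and the position of the bbx4-1 lesion is not given in the sources used here, so the value does not show which part of the transcript was covered. Because the gene that the label names was higher and not lower, every direction below refers to the column labelled bbx4-1, and the gene that names the line does not bear out that label as a loss of transcript. The 5 expressed genes within 10 loci on either side had log2 ratios between −0.039 for TIC55-II and 0.081 for AT2G24830, with ARF3 at 0.056, GDU4 at 0.003 and AT2G24860 at 0.078.

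**Figure D1:**
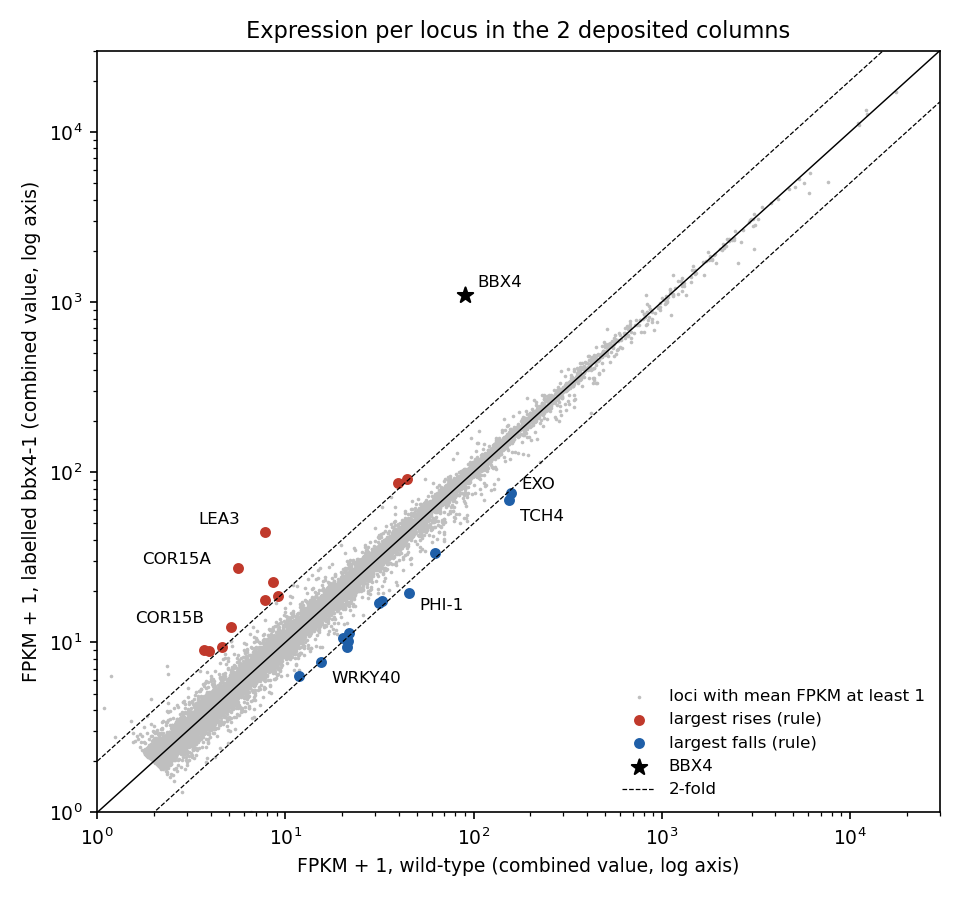
FPKM + 1 of every locus with mean FPKM of at least 1, wild-type on the horizontal and the column labelled bbx4-1 on the vertical axis, both logarithmic; each point is 1 locus, the solid line marks equal values and the dashed lines a 2-fold difference. BBX4 stands at 88.97 against 1095.7 FPKM, far above the line, while 90.8% of loci lie within 1.2-fold of equality.

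Apart from BBX4, few genes differed 2-fold between the columns. Of 18931 loci with mean FPKM of at least 1, 20 were at least 2-fold higher in the column labelled bbx4-1, BBX4 included, and 8 were at least 2-fold lower, together 0.148% of the loci. The median log2 ratio of all these loci was 0.028 with an SD across loci of 0.175, the central 95% ran from −0.33 to 0.35, and 90.8% lay within 1.2-fold. Of the 28 genes past 2-fold, 27 had an annotated length. All 27 differed by more than their 95% counting interval, and for 16 the difference exceeded 2-fold itself by that margin. These counts depended on the pseudocount, with 42 higher and 24 lower at 0.1 and 5 higher and 4 lower at 5. Among 9349 loci with mean FPKM of at least 10, the SD of the log2 ratio was 0.154 against a root mean square counting SE of 0.047. Smaller differences beyond counting error were therefore widespread. Without replicate columns, how many of them exceed the variation between seedlings is unknown.

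After BBX4, the highest ratios among nuclear genes with mean FPKM of at least 5 belonged to genes of several kinds. LEA3 (AT1G02820), a late embryogenesis abundant protein, stood at 6.81 FPKM in wild-type and 43.37 in the column labelled bbx4-1, a log2 ratio of 2.51 (SE 0.084). COR15A, a cold-induced protein of the chloroplast stroma, went from 4.62 to 26.37 FPKM, a log2 ratio of 2.28 (SE 0.070), and its tandem neighbour COR15B from 4.11 to 11.35 FPKM (1.27). Their values are uncertain where reads of these adjacent copies could not be told apart. The chitinase family gene AT2G43620 had a log2 ratio of 1.404, the lipid-transfer family gene AT4G12490 1.29 (2.68 to 8.01 FPKM), the thionin THI2.2, an antimicrobial peptide, 1.11, and AZI1, a lipid-transfer protein of systemic defence, 1.06. IGMT2, a methyltransferase of indole glucosinolates, was at 1.18 (2.95 to 7.95 FPKM), AT3G44450, which encodes the cryptochrome inhibitor BIC2, at 1.197, the phosphate-starvation RNA IPS1 at 1.03 (3.59 to 8.37 FPKM) and the RING/U-box gene AT1G24580 at 1.03. The other genes past 2-fold had mean FPKM under 5, and belong to a list or were chosen after their values were seen: PDF1.2, PDF1.2c, BBX29, PRR9, PR5, HIPP22 (0.94 to 3.64 FPKM), FAMT (0.24 to 1.76 FPKM) and the small nucleolar RNA gene AT4G26365 (0.51 to 2.47 FPKM).

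The 12 genes with the lowest ratios included 3 members of the list of touch and rapid stress genes, TCH4, WRKY40 and SZF1. TCH4, a xyloglucan endotransglucosylase known for its induction by touch, stood at 153.8 FPKM in wild-type and 67.45 in the column labelled bbx4-1, a log2 ratio of −1.18 (SE 0.024). PHI-1 was at −1.21 and its relative EXO, from 156.37 to 74.32 FPKM, at −1.06. The transcription factors DREB26, WRKY40 and WRKY18 had log2 ratios of −1.08, −1.03 and −0.88. The ethylene biosynthesis gene ACS6 was at −0.94, the zinc finger gene SZF1 at −0.90 and the mitochondrial dicarboxylate carrier gene DIC2 at −0.90. AT4G29780, annotated as a nuclease, was at −1.18, AT1G76600 at −0.93 and AT3G53250 at −0.90. Of the 8 genes past 2-fold, TCH4, PHI-1, EXO, DREB26, WRKY40 and AT4G29780 are among these, and the other two were AT2G24683 (1.81 to 0.32 FPKM) and ATMG00665, chosen after their values were seen. ATMG00665, a mitochondrial locus, stood at 5.55 FPKM in wild-type and was listed at 0 in the column labelled bbx4-1.

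Of the 28 gene lists, 7 had a median above the central 95% of matched random lists and 7 below it. A filter at mean FPKM 5 left 4 above, and unmatched random lists left 3 below. The list of touch and rapid stress genes stood farthest from its random lists in the downward direction. Its 11 measured members all had log2 ratios below 0, with a median of −0.53 (random lists −0.043 to 0.11). By more than their 95% counting interval, 10 of them were below 0. That margin alone does not set the list apart, since 5 of 10 reference genes passed it upwards and 1 downwards. Beyond TCH4, WRKY40 and SZF1, ERF5 was at −0.34 and CZF1 at −0.24, while TCH3, a calmodulin-like protein, was at −0.018. Chosen after their values were seen, TCH2 was at −0.53, WRKY33 at −0.55 and ZAT12 at −0.62. TCH4 is also a member of the list of expansins and xyloglucan-modifying (XTH) enzymes, and ERF5 and ERF6 of the ethylene list.

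**Figure D2:**
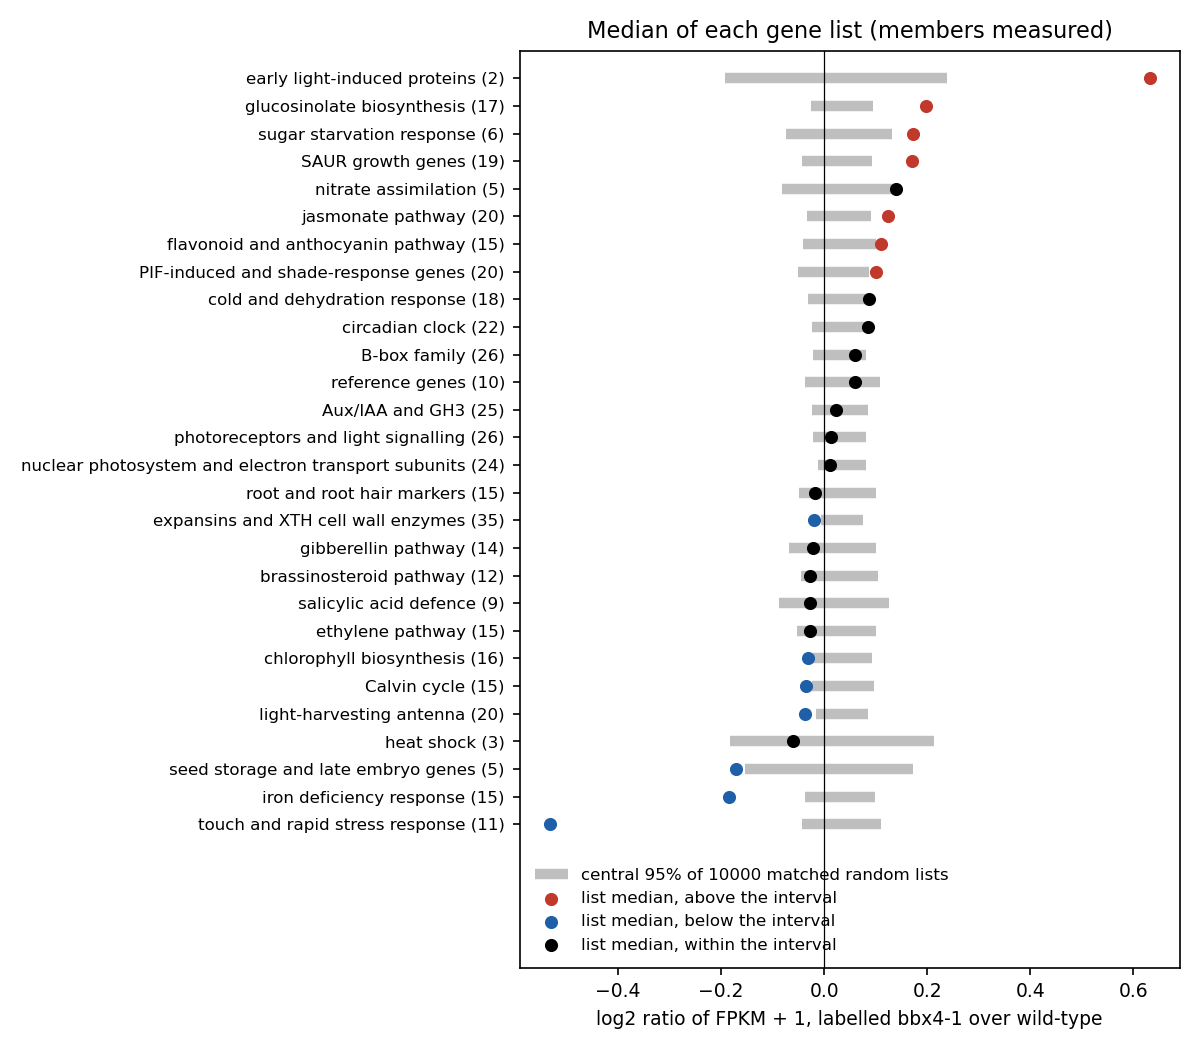
Median log2 ratio of FPKM + 1, column labelled bbx4-1 over wild-type, for the 28 gene lists, with the number of measured members in parentheses; points are list medians, coloured by whether they lie above, below or within the grey bar, which spans the central 95% of 10000 random lists matched on mean FPKM. Touch and rapid stress genes (−0.53) lie far below their bar, and glucosinolate genes (0.20) and the 2 early light-induced proteins (0.63) above theirs.

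Lists of light capture and carbon fixation genes were called below, each on a small median. The light-harvesting antenna list had a median of −0.037 (percentile 0.5), with 14 of 20 members below 0, the Calvin cycle list −0.035 (percentile 1.24), with 12 of 15 below 0, and the chlorophyll biosynthesis list −0.031 (percentile 1.12), with 10 of 16 below 0. The lowest members were LHCB1.4 at −0.21, GAPB at −0.18 and GUN4, a regulator of chlorophyll synthesis, at −0.15, whereas CP12-1 was at 0.23 and LHCB4.3 at 0.14. The antenna LHCB1 and the RBCS genes exist in near-identical copies, so the values of single members such as LHCB1.4 and RBCS1B (−0.11) are uncertain. These 3 calls ended with unmatched random lists, at percentiles 2.58, 5.43 and 5.07. The highest of the 10 matching bins spans a wide range, so genes such as LHCB1.1 (3096.5 FPKM in wild-type) were matched only coarsely. Nuclear photosystem and electron transport subunits lay within their random lists, with a median of 0.011 (−0.017 after TMM rescaling) over 24 members, PSBY at 0.11 and PETC at −0.048. The 2 early light-induced proteins, which bind chlorophyll under light stress, were higher, with ELIP1 at 0.86 and ELIP2 at 0.41. Plastid and mitochondrial transcripts were not among the lists fixed in advance, and were compared with random lists of nuclear genes. Plastid-encoded transcripts were lower as a group, with a median of −0.34 over 133 loci, 122 of them below 0, against random lists at 0.017 to 0.059. They took 9.63% of all FPKM in wild-type and 8.75% in the column labelled bbx4-1. Mitochondrial transcripts had a median of −0.38 over 36 loci, 34 of them below 0. The nuclear 18S ribosomal RNA loci AT3G41768 and AT2G01010, chosen after their values were seen, were at −0.46 and −0.63.

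Photoreceptor and light signalling genes as a list did not stand apart, with a median of 0.013 (−0.013 after TMM rescaling) and 13 of 26 members on each side of 0. The red-light receptor gene PHYB was at 0.17 (21.42 to 24.21 FPKM) and PIF3, a growth-promoting factor that phytochromes inactivate, at 0.13, while PIF5 was at −0.29 (34.83 to 28.38 FPKM). Genes induced by PIFs or shade had a median of 0.10 (percentile 99.0), with 15 of 20 members above 0. HFR1, a repressor of shade growth, was at 0.65 (3.94 to 6.75 FPKM) and BBX28, also a B-box family member, at 0.52, whereas PAR1, another such repressor, was at −0.39. The call ended with a filter at mean FPKM 5 (percentile 94.2). The flavonoid and anthocyanin list had a median of 0.11 (percentile 98.7), with 13 of 15 members above 0. FLS1, flavonol synthase, was at 0.65 (29.06 to 46.1 FPKM) and chalcone isomerase (CHI) at 0.38, while DFR, the anthocyanin-branch reductase, was at −0.074. This call ended at a pseudocount of 5 (percentile 95.4) and with the filter at mean FPKM 5 (percentile 95.4).

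Within the B-box family, the members went both ways, and the median of 0.060 over 26 measured members other than BBX4 lay within the random lists. The highest members were BBX29, BBX31 and BBX30. BBX29 was at 1.63 (1.34 to 6.25 FPKM, ratio 4.66 with a counting interval of 3.64 to 6.10), BBX31 at 0.95, BBX30 at 0.88 and, chosen after its values were seen, BBX32 at 0.83. BBX27, chosen in the same way because it has a single B-box as these do, was at −0.19. BBX20 was at −0.34, BBX14 at −0.33 (91.79 to 72.99 FPKM) and BBX3, a close relative of BBX4, at −0.26. Clock genes had a median of 0.085 (percentile 97.2), inside the interval, with 17 of 22 members above 0. PRR9 was at 1.44 (1.39 to 5.49 FPKM), GI at 0.78 (3.67 to 7.0 FPKM) and PRR7 at 0.42, while ELF4 was at −0.31. The clock list moved above the interval at a pseudocount of 0.1 (98.5), after TMM rescaling (97.6), with unmatched random lists (97.7) and with all listed loci kept (97.8), the last of these added after seeing the data.

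**Figure D3:**
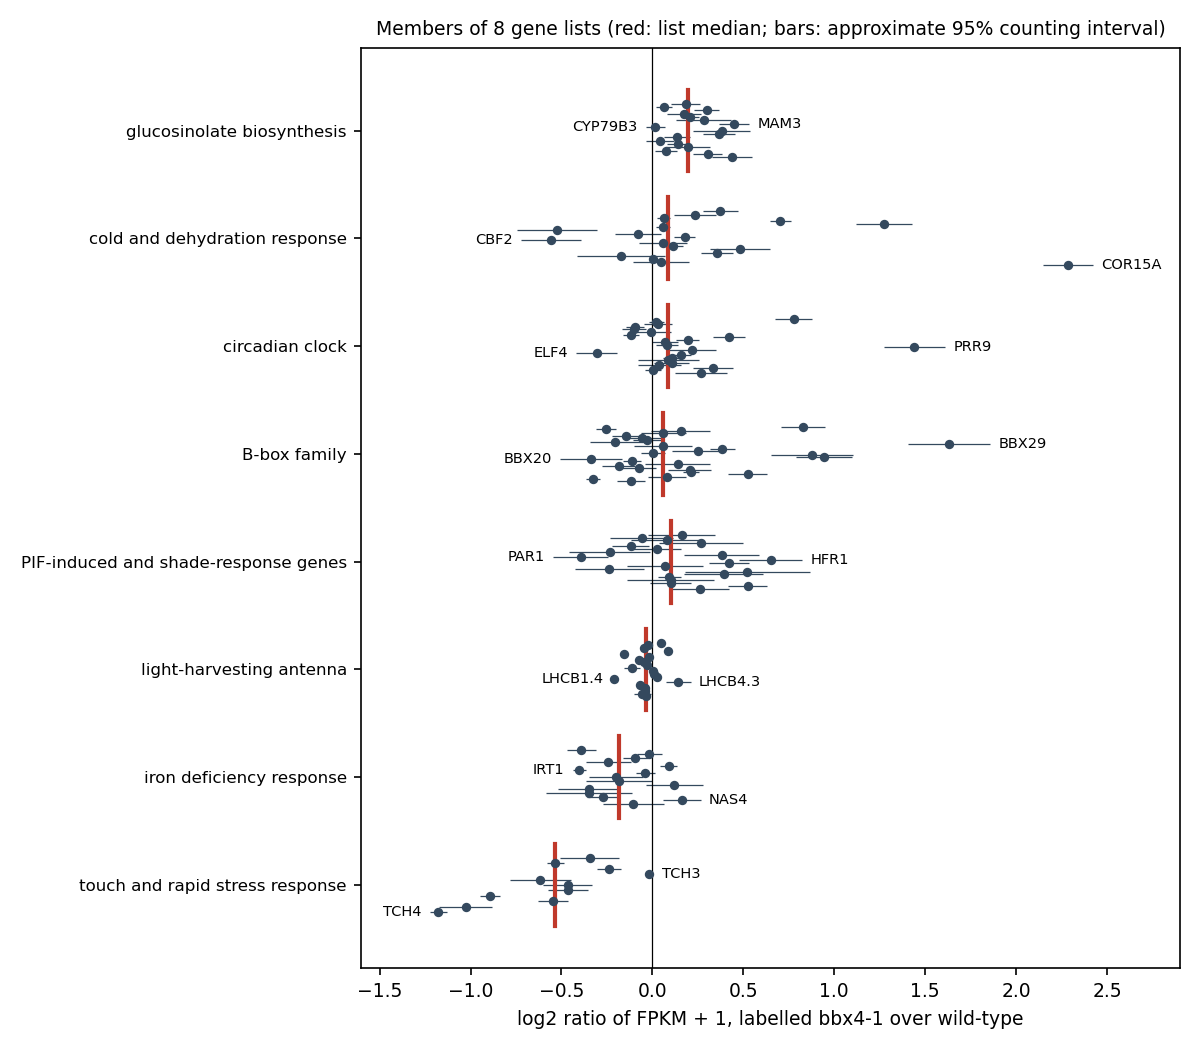
Log2 ratio of FPKM + 1, column labelled bbx4-1 over wild-type, for the measured members of 8 gene lists; each point is a gene with its approximate 95% counting interval, red bars are list medians, and the highest and lowest member of each list are named. All 11 touch genes lie at or below −0.018 and all 17 glucosinolate genes at or above 0.015 (the lowest, CYP79B3, at −0.012 after TMM rescaling), whereas the B-box and cold lists reach from below −0.33 to above 1.6.

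Growth and hormone lists differed in direction. SAUR growth genes had a median of 0.17 (percentile 99.99), with 16 of 19 members above 0 and SAUR20 at 0.57 and SAUR21 at 0.52. The SAUR19 to SAUR24 and SAUR61 to SAUR68 genes are near-identical copies in 2 clusters, so single values are uncertain, and the call ended with a filter at mean FPKM 5 (percentile 93.2). Expansins and XTH enzymes were called below with a median of only −0.020 (percentile 0.585) and 18 of 35 members below 0. XTH23 was at −0.65 and XTH16 at −0.57, but XTH24 was at 0.49 and EXPA1 at 0.36, and with unmatched random lists the call ended (percentile 3.38). Auxin-response genes of the Aux/IAA and GH3 families (median 0.023, and −0.001 after TMM rescaling) lay within their random lists, with GH3.2 at −0.46 and IAA11 at 0.27. So did the gibberellin list (−0.021, and 0.018 with a filter at mean FPKM 5), with GID1B at 0.31, and the brassinosteroid list (−0.027), with BRI1 at −0.12. The ethylene list (−0.027, and 0.011 without its members of lowest mean FPKM) also lay within its random lists, with ACS6 at −0.94. The brassinosteroid list fell below at percentile 2.32 without its members of lowest mean FPKM, among them BR6OX1, its highest by log2 ratio (0.18).

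Jasmonate genes had a median of 0.12 (percentile 99.84), with 14 of 20 members above 0, a call that ended with a filter at mean FPKM 5 (percentile 96.4). The defensin gene PDF1.2, a marker of jasmonate and ethylene signalling, was listed at 0.18 FPKM in wild-type and 5.30 in the column labelled bbx4-1, a ratio of 29.4 with a counting interval of 12.4 to 92.2. It has a close copy in PDF1.2c (0.09 to 3.1 FPKM), so their separate values are uncertain. CORI3 was at 0.55, while VSP2, a storage protein induced by jasmonate, was at −0.24 and JAZ7 at −0.35 (1.46 to 0.93 FPKM). The salicylic acid list lay within its random lists (−0.027), with PR5 at 1.02 (0.83 to 2.71 FPKM, a ratio of 3.27) and WRKY70 at −0.49. Cold and dehydration genes had a median of 0.087 (percentile 96.6), within the interval, with 14 of 18 above 0. Besides COR15A and COR15B, KIN2 was at 0.70 (105.45 to 172.45 FPKM), while the cold-response regulators CBF2 and CBF1 were at −0.56 (12.67 to 8.27 FPKM) and −0.52 (4.16 to 2.59 FPKM). The list lay above its interval at a pseudocount of 5 (percentile 99.2) and in 2 planned settings that drop members. These were a filter at mean FPKM 5 (median 0.18, percentile 100.0) and leaving out the members of lowest mean FPKM (median 0.14, percentile 99.96). The filter left out CBF1 and CBF3, and the other setting CBF3 (−0.17). In both settings all members left out were below the list median, so the median rose by construction. The 3 measured heat shock genes had a median of −0.060, within their interval, with HSP101 at −0.17 (3.73 to 3.21 FPKM).

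Among metabolic lists, the 17 measured glucosinolate biosynthesis genes all had log2 ratios above 0 as deposited, with a median of 0.20 (percentile 100.0). Of these genes, 15 were above 0 by more than their 95% counting interval. That margin was often passed in these columns: of 10 reference genes, 5 were above 0 and 1 below 0 by it. MAM3 was at 0.45, CYP79F2 at 0.44 and FMOGS-OX1 at 0.38, and the lowest, CYP79B3, was at 0.015 and turned to −0.012 after TMM rescaling. Iron deficiency genes were lower, with 12 of 15 members below 0 and a median of −0.19 (percentile 0.0). The iron transporter gene IRT1 went from 170.23 to 128.71 FPKM (−0.40), and the reductase gene FRO2 was at −0.39. Both are also root genes, and the list of root and root hair markers that holds them lay within its random lists (−0.018), with SCR at 0.21. Sugar starvation genes were called above with a median of 0.17 (percentile 99.5) over 6 members, of which ASN1, asparagine synthetase, was at 0.69 and DIN10 at −0.30. By more than the 95% counting interval, 3 members were above 0 and 2 below 0, so the call rests on few genes. Nitrate assimilation genes had a median of 0.14 over 5 members (percentile 97.1), within the interval, with the nitrate reductase gene NIA1 at 0.40. They were above at a pseudocount of 5 (percentile 98.0) and without the member of lowest mean FPKM (median 0.19, percentile 99.6). That member, HRS1, also had the lowest log2 ratio (−0.15), so leaving it out raised the median by construction. Seed storage and late embryo genes were called below on 5 members with a median of −0.17 (percentile 1.52), with OLEO2 at −0.38 and CRA1 at 0.19. That median is the value of PER1, whose counting interval of −0.37 to 0.027 includes 0. Only 1 member was below 0 and 1 above 0 by more than the 95% counting interval, so the call rests on little. Reference genes had a median of 0.059 over 10 members, within their random lists, with ACT2 at −0.076 and GAPC1 at 0.20.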

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

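The settings with nuclear loci alone and with all listed loci kept were tests chosen after seeing the data. A B-box list without BBX28 to BBX32 was computed too, but these are its 5 highest members, so their removal lowers the median by construction and it is not set against random lists here. No paired analysis was possible because the deposited tables hold no replicate columns, so the replicate numbers in the labels could not be used as a pairing, and leaving out each replicate in turn was not run for the same reason. The counts of genes past the threshold depended on the settings that define them. From 20 higher and 8 lower, they moved to 42 and 24 with a pseudocount of 0.1, to 5 and 4 with a pseudocount of 5, to 107 and 105 at a fold threshold of 1.5 and to 6 and 1 at a threshold of 3. A filter at mean FPKM 5 left 12 higher, because fewer genes with low values were counted. TMM rescaling, which shifted the median of all genes by −0.024, rescaling to equal totals, no filter and nuclear loci alone kept both counts within 1.5 times. BBX4 had a log2 ratio of 3.55 with a pseudocount of 5 and otherwise stayed at 3.58 or more. The number of lists called above went from 7 to 4 with the filter at mean FPKM 5, which ended the flavonoid, PIF and shade, SAUR and jasmonate calls and added the cold and dehydration list. The number called below went from 7 to 3 with unmatched random lists, which ended the antenna, Calvin cycle, chlorophyll and expansin and XTH calls. The filter also removed list members with low values, such as CBF1 and CBF3 of the cold list. Beyond that, the cause of these shifts in the lists was not tested. Touch, iron, seed storage, sugar starvation, glucosinolate and early light-induced lists kept their calls in all 8 planned settings that apply to lists. No called list and no named gene past 2-fold changed direction in those settings, and 5 of 170 named genes, all with log2 ratios near 0, changed sign: GAPA-1, UGT79B1, CYP79B3, TUB2 and PP2AA3, all after TMM rescaling. With 1 combined value per genotype, depth limits the precision of genes with low values, and the spread between seedlings stays unknown at any depth.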

Other observations

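The tests of the BBX4 value and of counting noise in the touch list were chosen only after those results were seen; those of the second early-response list, of small RNAs and of phosphate genes were written before their results. The 18S ribosomal RNA loci, the lipid-transfer genes, AT5G64120, ESM1 and BIC1 below were also picked after their values were seen, and the members of the second early-response list and of the phosphate list lie outside the rule for named genes.

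A run of lipid-transfer genes on chromosome 4, between 7401087 and 7439805 of TAIR10.1, was mostly higher in the column labelled bbx4-1. AZI1 went from 43.12 to 90.78 FPKM, EARLI1 from 31.73 to 61.75, AT4G12490 from 2.68 to 8.01, AT4G12500 from 0.38 to 1.43, AT4G12545 from 54.51 to 90.03 and AIR1 from 80.24 to 128.6. In the middle of the run, AT4G12510 differed less (88.29 to 103.06) and AT4G12520 went the other way (31.53 to 28.16). The genes resemble each other, and how reads were divided between them is not given in the sources used here. Among other defence genes, the peroxidase gene AT5G64120 was at 0.92 on the log2 scale. ESM1, which directs glucosinolate breakdown, was at 0.71, beside the biosynthesis genes of that pathway. Both cryptochrome inhibitor genes were higher, BIC2 (AT3G44450) at 1.197 and BIC1 (AT3G52740) at 0.43.

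BBX4 was 12.3-fold higher in the column labelled bbx4-1, the opposite of a loss of transcript; that column is headed BBX4, not bbx4-1, in its table. A scaling difference between the columns is argued against by the median log2 ratio of all loci, which was only 0.028. TMM rescaling shifted that median by −0.024, so the BBX4 log2 ratio of 3.58 after it follows from that small shift and is no separate test. Raised transcription of the whole region is argued against by the 5 expressed neighbours, whose median log2 ratio was 0.056. Exchanged labels cannot be told apart from a line that makes more BBX4 transcript, because 0 other genes are known from the labels to differ between the genotypes. An allele whose lesion leaves or raises transcription of part of the gene, or a line that overexpresses BBX4, stays open and was not tested, since the tables give no coverage along the gene.

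The touch and rapid stress genes were lower in the column labelled bbx4-1. Counting noise is argued against, since 10 of the 11 members were below 0 by more than their 95% counting interval. Reference genes often passed that interval too (5 of 10 upwards, 1 downwards), so the count speaks to counting error only. A second list of early-response genes, with no member in common with the first, had a median of −0.43 (percentile 0 of matched random lists), with 17 of 17 measured members below 0, among them ERF11 at −0.74 (4.06 to 2.03 FPKM), CAF1a at −0.67 and MYB44 at −0.13. This is consistent with a rapid stimulus response that differed between the 2 collections of seedlings, such as in handling at harvest, a hypothesis that needs replicates collected side by side. An effect of the genotype on these genes gives the same values and stays open.

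Plastid and mitochondrial transcripts were both lower, with medians of −0.34 and −0.38. Less carry-over of all RNA without a poly(A) tail predicted a fall of nuclear tRNA, snoRNA and snRNA too. Their 707 loci had a summed log2 ratio of 0.098 (counting interval 0.020 to 0.18), which was not a fall. Most of that sum was snoRNA, about 2185 of 2482 fragments in wild-type, while tRNA alone was at −0.14 (−0.38 to 0.11). The 18S ribosomal RNA loci were lower, AT3G41768 from 6040.55 to 4377.92 FPKM and AT2G01010 from 193.9 to 125.18. The sum therefore speaks mainly for snoRNA, and does not decide the question for RNA without a poly(A) tail as a whole. Less carry-over of ribosomal and organelle RNA in particular, or a lower organelle RNA content in the seedlings, stays open and was not tested.

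IPS1 being higher raised the hypothesis of a phosphate starvation response. A list of 11 other phosphate starvation genes had a median of 0.11 at percentile 97.39, just inside the upper limit, with 8 members above 0, among them PAP17 at 0.48 and AT4 at 0.41, so the hypothesis stayed undecided.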
